A study of Homo sapiens with 24 samples.

How the data were processed

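Total RNA was profiled in 4 human Ewing sarcoma cell lines (SKNMC, TC32, TC71 and RDES) on Illumina expression beadchips. Per the labels, cells were exposed for 24 h to 5 nM pladienolide B (PlaB) or to 0.1% DMSO vehicle, RNA was extracted with Trizol, and biotinylated cRNA was made with the TotalPrep-96 amplification kit. The sample descriptions call the controls DMSO vehicle, while the treatment protocol calls them untreated. They are called vehicle here. Samples were grouped by cell line and treatment, which gave 8 groups of 3 arrays. The labels number the samples of a group 1 to 3 and do not say whether they come from separate cultures or what the numbers share across groups.

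The deposited non-normalized table holds, per the file headers, one probe signal intensity per array on a linear scale, neither normalized nor background-subtracted, with values from 56.3 to 8894.51. Beside each intensity it holds a detection p-value, per the file headers. These p-values were multiples of 0.0013, the step that 770 negative control probes would give. The deposited series matrix holds log2 values, and the values showed that each line's 6 arrays had been quantile-normalized apart from the other lines. The submitters' processing notes name GenomeStudio, R 3.0.2 and lumi without saying which step each did. The chip and position of each array are not given in the sources used here.

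The comparisons were run on the non-normalized intensities. Rows of the series matrix were compared with log2 intensities that had been quantile-normalized within each line, at a tolerance of 0.03 log2. They matched for 99.996% of probes in TC32 but for 36.4% in SKNMC, 75.2% in TC71 and 36.4% in RDES. The series matrix was therefore used only as an alternative for TC32.

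Intensities were processed with limma 3.58.1 in R 4.3.3. Background was estimated from the detection p-values, an offset of 16 was added, and arrays were quantile-normalized on the log2 scale (the neqc method). A probe was kept if its detection p was under 0.05 on all 3 arrays of at least 1 of the 8 groups, which left 17557 of 47323 probes. Gene symbols came from the annotation supplied with the series matrix: 30112 probes had 1 symbol, 8 had several and 17203 had none. Among the tested probes the numbers were 13978, 1 and 3578, and they covered 10882 genes. Entrez identifiers of 30073 probes were looked up in a RefSeq gene table (assembly GRCh38.p14), and 0 symbols needed an update. That table also gave the class of each RNA. The deposited files name no genome build, so no positions are given.

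A group-means model was fitted by limma to all 24 arrays, with empirical Bayes moderation (16 residual and 13.4 prior degrees of freedom). The comparisons were PlaB against vehicle in each line, the mean of the 4 within-line differences, the probes changed the same way in all 4 lines, and a moderated F-test of whether the response differed between lines with its 6 pairwise follow-ups. P-values are two-sided and Benjamini-Hochberg adjusted over all tested probes, with a threshold of 0.05. Fold changes are PlaB over vehicle on the log2 scale.

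Gene lists of 22 kinds were fixed before the data were examined, as were the tests, the filter and most of the alternatives. They covered EWS-FLI1-activated and EWS-FLI1-repressed genes, SF3a/SF3b and U2 snRNP-associated factors, SR proteins and hnRNPs, replication-dependent histone genes, other single-exon genes, p53 targets, unfolded-protein and amino-acid stress response genes, and heat shock protein genes. They also covered G2/M, DNA replication, BCL2-family, cytosolic ribosomal protein, oxidative phosphorylation, immediate-early, interferon-stimulated, snoRNA host and cholesterol synthesis genes, and fibroblast and mesenchymal, epithelial, blood-cell and endothelial markers. Each list was tested with camera (preset correlation 0.01) on the brightest probe of each gene, with p-values adjusted over 95 tests of 19 lists. The 3 lists with fewer than 5 measured genes were not tested. Camera was also run with an estimated correlation. The fry test was run beside it and asks whether the genes of a list move on balance one way, without comparing them with other genes.

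The genes named in the report were chosen by a rule fixed beforehand. The rule took 12 preset genes and the 10 genes that rose and the 10 that fell most in the mean of the lines, with no overlap between arrays and detection in both groups of every line. It also took the 5 that rose and the 5 that fell most in each line, the 8 with the widest range of response between lines, and up to 4 members of each list with the largest mean change. Last, it took genes detected on every array of one treatment and on no array of the other. A gene is read from its brightest tested probe. FLI1 and MDM2 had no probe past the filter, and NR0B1 was not analysed here. Y-linked genes and XIST were left out of the named genes.

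Arrays give no read depth, and their number limits the precision. Depth is given as the number of probes detected per array, from 13821 to 18736. The scripts were tested on simulated data with probes changed by known amounts. Of probes changed 1.5-fold, 74.6% to 91.0% were recovered in a single line, 100% in the mean, 52.2% as changed in all 4 lines and 29.9% as differing between lines. Probes changed 2-fold were recovered at 98.5% or more, with 0 to 23 false calls among 17557 probes. A simulated list lowered by 0.5 log2 was recovered, and 0 of the other lists were called. The simulated noise was independent between genes, most probes were left unchanged, and normalization was not repeated. False calls of lists or probes in the real arrays are therefore not measured by it.

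The alternatives tried were no background correction, an offset of 50, median centring, cyclic loess, no filter, a detection threshold of 0.01, array weights, the replicate number as a block, 1 probe per gene, a variance prior with trend and robust estimation, only the 6 arrays of a line, the series matrix for TC32, a 2-fold minimum, and leaving out each array in turn. For the lists they were an estimated correlation, lists without shared genes, and the mean of all probes of a gene. Median centring on probes detected on all arrays and quantile normalization within each line without background correction were added after the data were seen.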

Results

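Gene expression was measured on beadchips in SKNMC, TC32, TC71 and RDES, lines from Ewing sarcoma, a bone and soft-tissue tumour driven in most cases by a fusion of EWSR1 with FLI1. Each line received 5 nM PlaB, which binds the SF3b complex of the spliceosome and inhibits pre-mRNA splicing, or 0.1% DMSO for 24 h. The 24 arrays form 8 groups of 3. Nothing in the labels says that the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which can be technical. Correlations across probes were 0.987 to 0.994 between arrays of a group, 0.922 to 0.960 between treatments of a line, and 0.850 to 0.940 between lines (probes are not independent replicates).

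Arrays detected between 13821 and 18736 probes, or 29.2% to 39.6% of those on the chip. In SKNMC the mean was 16627 ± 169 with vehicle and 14654 ± 726 with PlaB (SD, n = 3), a difference of -11.9%. The differences were -12.0% in TC32, -7.48% in TC71 and -7.61% in RDES, and only in TC71 did single arrays of the 2 treatments overlap. Averaged over lines, PlaB arrays detected fewer probes (difference -1663.5, exact two-sided permutation p = 2.5e-05 over 160000 regroupings within lines).

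**Figure D1:**
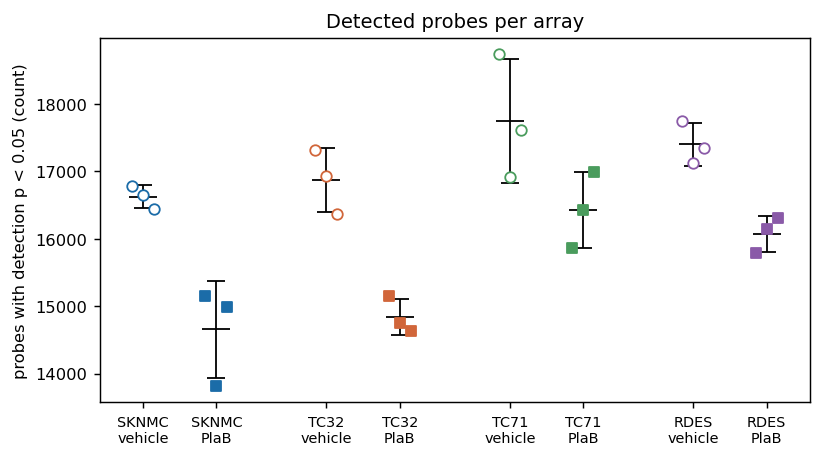
Number of probes with detection p under 0.05 on each array (vertical axis, count), by line and treatment; open circles are vehicle, filled squares PlaB, and black marks the mean and SD of 3 arrays. The vertical axis does not start at 0, and PlaB means lie between 14654 and 16427 against 16627 to 17755 with vehicle.

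The mean of the 4 within-line differences addressed how the transcriptome of Ewing sarcoma cells differs after a day of SF3b inhibition. SF3B1, the SF3b subunit that contacts the branch point and carries the drug's binding site, rose by 0.68 ± 0.06 log2 (SE, 12 PlaB and 12 vehicle arrays; adjusted p = 7.5e-12; probe ILMN_1706075). Its level in SKNMC went from 8.88 ± 0.19 to 9.51 ± 0.08 log2 (SD, n = 3). It rose in each line, with the TC32 rise not called in 1 of 7 ways of scaling (adjusted p = 0.18). PHF5A, another SF3b subunit at the same site, rose by 0.33 ± 0.05, with adjusted p = 0.10 under median centring. HNRNPH1, a splicing regulator that acts on the EWSR1 part of some fusion transcripts, fell by 0.58 ± 0.05 (adjusted p = 5.7e-11). NKX2-2 and CCND1, a transcription factor and a cyclin that EWS-FLI1 activates, fell by 0.66 ± 0.06 and 0.52 ± 0.05.

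Several preset genes did not pass in the mean. EWSR1 had a value of 0.13 ± 0.06 (adjusted p = 0.056). It was called upward in several other settings, at 0.12 with an offset of 50 and 0.21 with centring on probes detected on all arrays, and was -0.07 under median centring. Its 2 other probes were called in opposite directions, at -0.31 and 0.22. The transcription factor MYC stood at -0.07 ± 0.06, with -0.23 and a call under median centring and 0.04 with centring on probes detected on all arrays. The survival factor MCL1 stood at 0.05 ± 0.08, with -0.23 and a call under median centring and -0.00077 without RDES vehicle replicate 2. CDKN1A, the p21 cell cycle inhibitor, had a mean of -0.03 ± 0.06 (called at -0.31 under median centring and at -0.09 without background correction) and opposite responses in the lines, given further on.

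Among genes detected in both groups of every line, with no overlap between arrays, the largest rises common to the 4 lines included probes for small nucleolar RNAs. These RNAs guide chemical modification of ribosomal and spliceosomal RNA. Whether their probes read mature RNA or longer precursors was not tested, here and for the small RNAs named below. SNORD16 rose by 2.40 ± 0.06 log2 (adjusted p = 2.4e-23), SNORD55 by 2.35 ± 0.07, SNORA7B by 2.09 ± 0.06, SNORA3B by 2.02 ± 0.06 and SNORD100 by 1.83 ± 0.05. Without background correction the last 4 rose by 1.25, 1.24, 1.13 and 1.06. SNHG1, a noncoding RNA whose introns hold snoRNAs, rose by 2.08 ± 0.05. The purinergic receptor gene P2RY11 rose by 2.15 ± 0.06, PDRG1 by 1.96 ± 0.06, the tumour suppressor RASSF1 by 1.84 ± 0.05 and the nucleoporin gene NUP50 by 1.83 ± 0.05. In the setting used, the largest fall among these genes was that of DBNL, an actin-binding adaptor (-2.35 ± 0.05, limma adjusted p = 9.6e-25). The membrane protein TMEFF2 (-2.23 ± 0.06) and the fatty acid desaturase FADS1 (-2.20 ± 0.06) came next. They were followed, in the same set, by the splicing factor SRSF7 (-2.18 ± 0.08), the complex I assembly factor NDUFAF3 (-2.03 ± 0.05), protein kinase C beta, PRKCB (-2.01 ± 0.06), and nonmuscle myosin MYH10 (4.01-fold lower). PAAF1, CCDC90B and the complex III assembly factor UQCC2 fell by 1.97 ± 0.06, 1.89 ± 0.06 and 1.88 ± 0.05.

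Among SF3a/SF3b and U2 snRNP-associated factors, 18 of 26 measured genes rose, 3 fell and 5 did not pass (also 18 and 3 adjusted over the list alone). The list rose with a median of 0.34 log2 (camera adjusted p = 0.0014). SF3B4 rose by 1.17 ± 0.05, CHERP by 0.98 ± 0.06 and SF3A2 by 0.86 ± 0.05, while the RNA helicase DDX46 fell by 0.90 ± 0.06. SR proteins and hnRNPs, which bind pre-mRNA and steer splice site choice, moved both ways: 17 of 37 rose and 15 fell (17 and 15 adjusted over the list alone), and the list was not called (adjusted p = 0.71). Its median was 0.04, its mean -0.01 and its median under median centring -0.16. Besides SRSF7, HNRNPA0 fell by 1.06 ± 0.05 and SRSF3 by 1.04 ± 0.07, and the kinase CLK3, which phosphorylates SR proteins, rose by 1.40 ± 0.06.

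EWS-FLI1-activated genes fell: 24 of 34 measured members fell and 3 rose (24 and 3 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.00044). After PRKCB, the largest falls in the list were those of the kinase VRK1 (-1.53 ± 0.07), the phosphatase inhibitor PPP1R1A (-1.21 ± 0.06) and the metalloreductase STEAP2 (-1.18 ± 0.06). EWS-FLI1-repressed genes were not called (adjusted p = 0.78), with 8 of 25 up and 8 down, the same adjusted over the list alone. Their median was 0.03 and their mean -0.01, and the median was -0.19 under median centring and -0.0077 under cyclic loess. In that list the matricellular gene CCN1 rose by 0.63 ± 0.06 and PHLDA1 by 0.49 ± 0.06, and the collagens COL1A1 and COL3A1 fell by 0.70 ± 0.06 and 0.62 ± 0.07.

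Genes of DNA replication fell: 24 of 32 fell and 3 rose (24 and 3 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.00023). By line the fall was called in TC71 and RDES, and not in SKNMC or TC32 (camera adjusted p = 0.51 and 0.0504). CDC45, part of the replicative helicase, fell by 1.81 ± 0.06, the ribonucleotide reductase subunit RRM2 by 1.55 ± 0.06, the primase PRIM1 by 1.52 ± 0.06 and GINS2 by 1.05 ± 0.06. G2/M genes were not called in the mean (adjusted p = 0.43): 15 of 32 rose and 11 fell, the same adjusted over the list alone, and their median of 0.09 was -0.09 under median centring. HMMR and the kinesin KIF11 fell by 1.17 ± 0.06 and 1.06 ± 0.06, and the kinase NEK2 and the ubiquitin-conjugating enzyme UBE2C rose by 0.96 ± 0.06 and 0.87 ± 0.06.

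SnoRNA host genes rose most of the lists, with 9 of 11 up and 1 down (9 and 1 adjusted over the list alone) and a median of 0.85 (adjusted p = 9.7e-05). SNHG7 rose by 1.49 ± 0.06, SNHG9 by 1.20 ± 0.06 and ZFAS1 by 1.13 ± 0.06. Oxidative phosphorylation genes fell, 24 of 43 down and 4 up (24 and 4 adjusted over the list alone), with a median of -0.19 (adjusted p = 0.0037, and adjusted p = 0.13 in TC71 alone). They included the ATP synthase subunits ATP5PO (-1.25 ± 0.06) and ATP5F1C (-0.85 ± 0.10) and UQCRC1 of complex III (-0.95 ± 0.05). NDUFB5 of complex I fell by 0.85 ± 0.06.

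The unfolded-protein and immediate-early lists rose with calls that depended on the correlation used, and heat shock protein genes were not called. Unfolded-protein and amino-acid stress response genes rose, 16 of 27 up and 7 down (17 and 7 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.023, and adjusted p = 0.12 with an estimated correlation). ATF3 rose by 1.67 ± 0.06, DDIT3, which encodes the stress factor CHOP, by 1.52 ± 0.05, PPP1R15A by 1.52 ± 0.06 and the amino acid transporter subunit SLC3A2 by 1.15 ± 0.06. Centring on probes detected on all arrays gave that list an adjusted p of 0.060. Immediate-early genes rose, 12 of 20 up and 1 down (12 and 1 adjusted over the list alone), with a median of 0.23 (adjusted p = 0.0077, and adjusted p = 0.087 with an estimated correlation). Under median centring the medians were 0.02 for immediate-early and 0.10 for unfolded-protein genes. ZFP36, which destabilizes mRNAs, rose by 0.76 ± 0.07. Heat shock protein genes had 9 of 17 up and 4 down (9 and 4 adjusted over the list alone) and a median of 0.22, and were not called (adjusted p = 0.12). The co-chaperone gene BAG3 rose by 0.99 ± 0.06, DNAJB6 by 0.91 ± 0.06, DNAJA1 by 0.81 ± 0.06 and HSPA1B by 0.61 ± 0.06.

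Cholesterol synthesis genes fell, 9 of 14 down and 3 up (9 and 3 adjusted over the list alone), with a median of -0.56 (adjusted p = 0.019, and adjusted p = 0.087 with an estimated correlation). By line they were called in SKNMC and TC71, and not in TC32 or RDES (camera adjusted p = 0.078 and 0.053). DHCR7, the last enzyme of the pathway, fell by 1.59 ± 0.06, LSS by 1.32 ± 0.06, HMGCS1 by 1.13 ± 0.06 and PMVK by 0.96 ± 0.07. Fibroblast and mesenchymal markers fell, 11 of 15 down and 1 up (12 and 1 adjusted over the list alone), with a median of -0.33 (adjusted p = 0.026, and adjusted p = 0.13 with an estimated correlation). By line these markers were called only in SKNMC (camera adjusted p = 0.16 in TC32, 0.47 in TC71 and 0.077 in RDES). PDGFRB fell by 1.12 ± 0.07 and COL5A1 by 0.91 ± 0.06, and the member that rose was TAGLN (1.40 ± 0.06). Under cyclic loess the adjusted p of these markers was 0.054. Without genes shared between lists it was 0.12, and that of the unfolded-protein list 0.11.

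The other lists were not called in the mean. P53 targets had 7 of 18 up and 5 down (7 and 6 adjusted over the list alone; adjusted p = 0.63). Their median of 0.02 was -0.06 under median centring. AEN, GADD45A and SESN2 rose by 1.04 ± 0.07, 0.73 ± 0.07 and 0.72 ± 0.06. BAX, a pore-forming death effector in that list and in the BCL2 family, fell by 1.12 ± 0.06, although a dimmer probe of BAX had a value of 0.03 and was not called. BCL2-family genes had 7 of 15 up and 5 down, the same adjusted over the list alone (adjusted p = 0.79). Their median was 0.05, their mean -0.03, and their median -0.21 under median centring. BCL2L2 fell by 0.92 ± 0.05, and HRK and BCL2L1 rose by 0.59 ± 0.07 and 0.46 ± 0.05. A dimmer BCL2L1 probe stood at -0.02.

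Replication-dependent histone genes had 5 of 20 up and 5 down in the mean, the same adjusted over the list alone (adjusted p = 0.57). Their median of 0.05 was -0.06 under median centring. H4C3 fell by 1.02 ± 0.06, and H2AC19, H2AC18 and H2AC25 rose by 0.95 ± 0.07, 0.88 ± 0.07 and 0.57 ± 0.07. Other single-exon genes, which need no splicing, had 15 of 45 up and 18 down (15 and 19 adjusted over the list alone; adjusted p = 0.68). Their median of -0.07 was 0.14 with centring on probes detected on all arrays. The neural transcription factors POU3F2, BHLHE22 and POU3F1 fell by 1.40 ± 0.07, 0.96 ± 0.08 and 0.84 ± 0.06, and KTI12 rose by 0.93 ± 0.05. Interferon-stimulated genes had 5 of 24 up and 12 down, the same adjusted over the list alone (adjusted p = 0.71). Their median of -0.11 was 0.09 with centring on probes detected on all arrays. IRF9 and IRF1 rose by 0.98 ± 0.06 and 0.39 ± 0.09, and HERC5 and IFIH1 fell by 0.88 ± 0.06 and 0.43 ± 0.06.

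Cytosolic ribosomal protein genes moved little, with 13 of 48 up and 8 down, the same adjusted over the list alone (adjusted p = 0.50). Their median of 0.04 was -0.05 under median centring. RPS23 rose by 0.99 ± 0.06, RPL29 by 0.38 ± 0.06 and RPL37 by 0.33 ± 0.08, and RPL7A fell by 0.34 ± 0.06. A dimmer RPL37 probe stood at 0.14 and was not called (adjusted p = 0.064). Markers of other cell types were few. Of 3 epithelial markers KRT18 rose (0.26 ± 0.07), and KRT8 and CLDN7 stood at 0.00 and -0.05. Of 3 blood-cell markers CD14 and CD79A rose by 0.91 ± 0.06 and 0.27 ± 0.07 and CORO1A fell by 0.34 ± 0.06. A second CD79A probe stood at -0.08 and was not called. The calls of KRT18, CD79A, RPL29 and RPL37 were lost under median centring, and that of CORO1A with centring on probes detected on all arrays. Of 2 endothelial markers ESAM, detected on 1 of 12 vehicle arrays, was at least 1.71-fold higher in SKNMC and 2.28-fold in TC71. CLDN5 was detected in no group but TC71 vehicle, so its mean value of -0.10 (limma adjusted p = 0.049) rests on background in the other groups. With centring on probes detected on all arrays its log2 fold change turned to 0.15 and was called upward (limma adjusted p = 0.033).

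**Figure D2:**
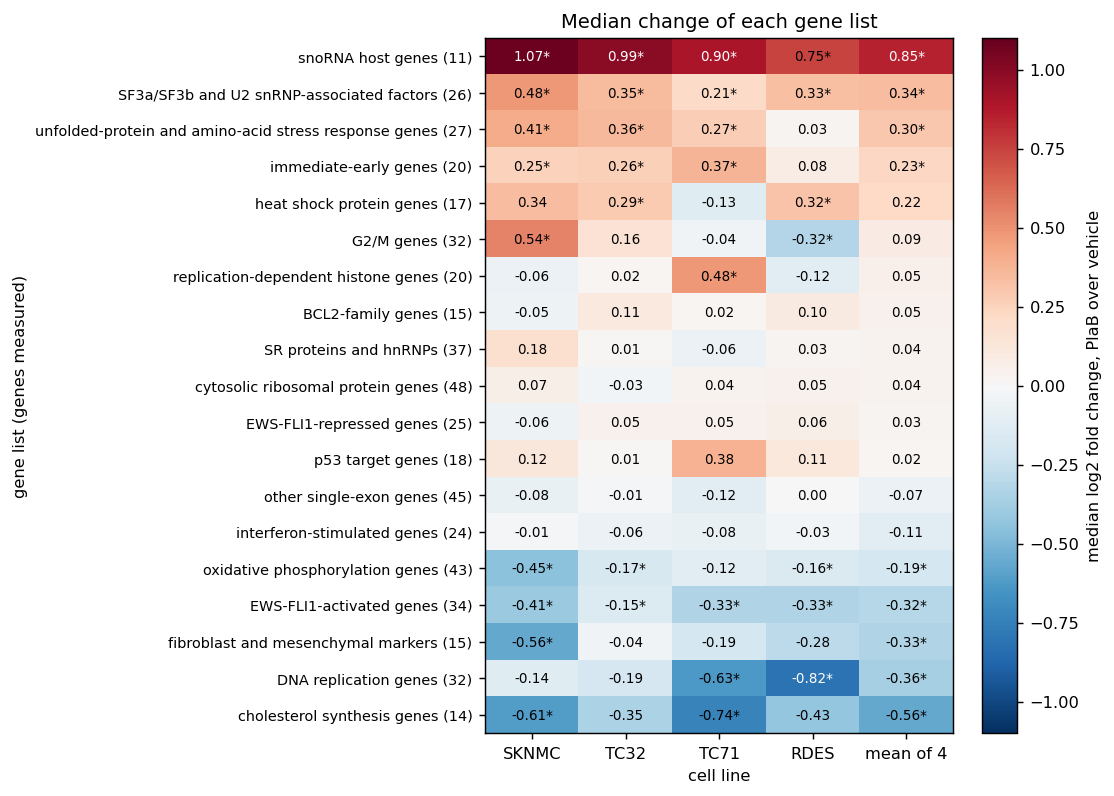
Median log2 fold change (colour and number, PlaB over vehicle) of the measured genes of 19 gene lists in each line and in the mean of the 4 lines; an asterisk marks lists with a camera adjusted p under 0.05. SnoRNA host genes had the highest median in every column, and the mean columns of SR proteins, histones, p53 targets, G2/M, BCL2-family, ribosomal protein and EWS-FLI1-repressed genes turned negative under median centring.

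In the mean of the lines, 11522 of 17557 probes changed (5429 up and 6093 down), 402 up and 455 down by 2-fold or more. The split depended on the scaling: median centring, which moved the median of all probes by -0.12 log2, gave 2914 up and 8345 down. Centring on probes detected on all arrays moved it by 0.15 and gave 8455 up and 4528 down. Of the 19 lists tested, 9 were called, 4 up and 5 down, and 5 were called with an estimated correlation. Fry, which makes no comparison with other genes, also passed for lists that camera did not call. Its adjusted p was 1.1e-09 for heat shock protein, 2.8e-06 for other single-exon and 0.00010 for interferon-stimulated genes. It was 0.0012 for histone and ribosomal protein, 0.0013 for G2/M and 0.0022 for p53 target genes. Fry did not pass for BCL2-family genes (0.11), EWS-FLI1-repressed genes (0.63) or SR proteins and hnRNPs (0.94). The medians of the called lists moved with the scaling. Over 7 ways of scaling they ranged from 0.55 to 0.86 for snoRNA host genes, 0.18 to 0.45 for SF3a/SF3b and U2 factors, -0.44 to -0.17 for EWS-FLI1-activated genes and -0.61 to -0.26 for DNA replication genes. The ranges were -0.35 to -0.07 for oxidative phosphorylation genes, -0.76 to -0.21 for cholesterol synthesis genes and -0.46 to -0.18 for fibroblast and mesenchymal markers.

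**Figure D3:**
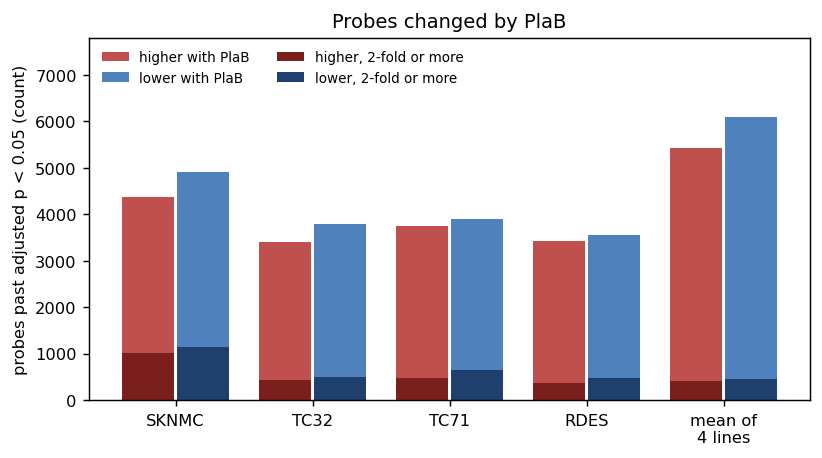
Number of probes past an adjusted p of 0.05 (vertical axis, count) in each line and in the mean of the 4 lines, split by direction; the dark lower part of each bar is the share at 2-fold or more. SKNMC had 9276 changed probes and RDES 6967, and the split by direction moved with the scaling, to 2226 up and 6653 down in SKNMC under median centring.

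In SKNMC, with the setting used, OVGP1, P2RY11 and SNORD13 rose most among genes with a symbol that were detected in both groups without overlap. The rises were 3.26 ± 0.13, 3.17 ± 0.12 and 3.17 ± 0.14 log2 (SE, n = 3 and 3, limma adjusted p = 4.9e-18, 2.4e-18 and 1.5e-17). SNORD13, a snoRNA that acts in 18S ribosomal RNA maturation, went from a level of 5.18 to 8.35. SNORA68 and SNORD99 rose by 2.97 ± 0.14 and 2.77 ± 0.11. A probe for 28S ribosomal RNA, RNA28SN5, fell by 3.72 ± 0.34, the growth-arrest gene GAS1 by 3.40 ± 0.15 and the stromal antigen CD248 changed by -3.15 ± 0.14. NDUFAF3 and the methionine sulfoxide reductase MSRB1 fell by 2.91 ± 0.10 and 2.78 ± 0.13. G2/M genes rose in this line, 20 of 32 up and 6 down (21 and 6 adjusted over the list alone; median 0.54, camera adjusted p = 0.0012). Oxidative phosphorylation genes fell, 28 of 43 down and 1 up (28 and 1 adjusted over the list alone; median -0.45, adjusted p = 0.00020). SnoRNA host genes rose (median 1.07, adjusted p = 0.00044), as did SF3a/SF3b and U2 factors (0.48, adjusted p = 0.0014), and EWS-FLI1-activated genes fell (-0.41, adjusted p = 0.012).

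Cholesterol synthesis genes and fibroblast and mesenchymal markers also fell in SKNMC, with medians of -0.61 and -0.56 (adjusted p = 0.0096 and 0.023, and adjusted p = 0.062 and 0.12 with an estimated correlation). Unfolded-protein and immediate-early genes rose, with medians of 0.41 and 0.25 (adjusted p = 0.026 and 0.024, and adjusted p = 0.13 and 0.15 with an estimated correlation). The unfolded-protein call held in 6 of 7 ways of scaling. Over these, the medians in SKNMC ranged from -0.53 to -0.15 for EWS-FLI1-activated genes, -0.60 to -0.21 for oxidative phosphorylation genes, 0.26 to 0.65 for G2/M genes and 0.29 to 0.68 for SF3a/SF3b and U2 factors. They ranged from -0.81 to -0.24 for cholesterol synthesis genes, -0.80 to -0.33 for fibroblast and mesenchymal markers, 0.14 to 0.53 for unfolded-protein genes and 0.10 to 0.48 for immediate-early genes. In all, 9276 probes changed, 4372 up and 4904 down, with 1015 and 1139 at 2-fold or more. The split was 2226 and 6653 under median centring, which moved the median of all probes by -0.14. It was 7326 and 3836 with centring on probes detected on all arrays, which moved it by 0.25.

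In TC32, SNORD13 rose by 3.24 ± 0.14 log2 (n = 3 and 3; limma adjusted p = 5.8e-17), SNORD16 by 2.74 ± 0.13, PDRG1 by 2.30 ± 0.11 and SNORA3B by 2.22 ± 0.11. RNA28SN5 rose by 2.64 ± 0.34. The chemokine gene CXCL14 fell by 3.01 ± 0.10, to a level of 5.98, and other falls were those of TMEFF2 (-2.39 ± 0.11), the secreted glycoprotein OLFM1 (-2.23 ± 0.13), SRSF7 (-2.21 ± 0.15) and the second-step splicing factor CDC40 (-2.10 ± 0.12). A second OLFM1 probe for another transcript stood at -0.27 in TC32, and at 1.20 in SKNMC and 1.65 in TC71. SnoRNA host genes rose (9 of 11 up and 0 down, also adjusted over the list alone; median 0.99, camera adjusted p = 7.0e-07). SF3a/SF3b and U2 factors rose (0.35, adjusted p = 0.0016), and EWS-FLI1-activated and oxidative phosphorylation genes fell (-0.15 and -0.17, adjusted p = 0.0097 and 0.019). The unfolded-protein list rose (0.36, adjusted p = 0.0018). DNA replication genes had 14 of 32 down and 4 up (14 and 5 adjusted over the list alone). Their median was -0.19, and they narrowly missed the threshold (camera adjusted p = 0.0504). Under median centring the medians of SF3a/SF3b and U2 factors and of the unfolded-protein list were 0.0058 and 0.041, and those of EWS-FLI1-activated and oxidative phosphorylation genes -0.51 and -0.53, with the calls kept. Heat shock and immediate-early genes were called upward with medians of 0.29 and 0.26 (adjusted p = 0.027 and 0.046, and adjusted p = 0.087 and 0.19 with an estimated correlation), but those calls held in only 4 and 2 of 7 ways of scaling, and the medians were -0.10 and -0.01 under median centring.

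The number of changed probes in TC32 was 7189, with 3393 up and 3796 down, and 439 and 505 at 2-fold or more. Median centring moved the median of all probes by -0.17 and gave 1181 up and 6301 down, and centring on probes detected on all arrays moved it by 0.19 and gave 5936 and 3092.

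In TC71, SNORD25 rose by 2.99 ± 0.13 log2 (n = 3 and 3; limma adjusted p = 6.0e-17), SNORD16 by 2.89 ± 0.13, SNORD13 by 2.60 ± 0.14 and DDIT3 by 2.58 ± 0.10. H2AC19, a histone H2A gene, rose by 2.41 ± 0.14. The stearoyl-CoA desaturase SCD fell by 2.78 ± 0.12, the podosome scaffold SH3PXD2A by 2.52 ± 0.11, PIGP of GPI anchor synthesis by 2.48 ± 0.10, FADS1 by 2.47 ± 0.13 and DBNL by 2.45 ± 0.10. Replication-dependent histone genes rose here, 13 of 20 up and 1 down (13 and 1 adjusted over the list alone; median 0.48, camera adjusted p = 0.0012). DNA replication genes fell, 24 of 32 down and 1 up (24 and 1 adjusted over the list alone; median -0.63, adjusted p = 1.1e-07). SnoRNA host genes rose (0.90, adjusted p = 0.00026), immediate-early genes rose (0.37, adjusted p = 0.00082), and EWS-FLI1-activated genes and cholesterol synthesis genes fell (-0.33 and -0.74, adjusted p = 0.00032 and 0.0016).

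SF3a/SF3b and U2 factors and the unfolded-protein list were called upward in TC71 with medians of 0.21 and 0.27 (adjusted p = 0.016 and 0.046, and adjusted p = 0.059 and 0.16 with an estimated correlation). The call of the unfolded-protein list held in 4 of 7 ways of scaling. Without background correction the medians in TC71 were -0.16 for EWS-FLI1-activated genes, -0.35 for cholesterol synthesis genes, 0.18 for histone genes, 0.18 for immediate-early genes, 0.16 for the unfolded-protein list and -0.49 for DNA replication genes. In TC71, 7648 probes changed, 3754 up and 3894 down, with 466 and 647 at 2-fold or more. Median centring gave 2125 and 5112. With centring on probes detected on all arrays, which moved the median of all probes by 0.12, the split was 4714 and 3442.

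In RDES, SNORD55 and SNORD25 rose by 2.33 ± 0.14 and 2.33 ± 0.13 log2 (n = 3 and 3; limma adjusted p = 4.7e-14 and 3.3e-14). The smooth-muscle actin ACTG2 rose by 2.08 ± 0.14, and the cytokine receptor subunit IL20RB and UBFD1 by 1.95 ± 0.13 and 1.95 ± 0.11. DBNL fell by 2.47 ± 0.10, the anthrax toxin receptor ANTXR1 by 2.42 ± 0.12, FADS1 by 2.26 ± 0.13, the recombination factor RAD51AP1 by 2.25 ± 0.13 and PI15 by 2.17 ± 0.11. Other ANTXR1 probes moved far less, with -0.38, -0.11 and 0.02 in RDES. The last, the dimmest, stood at 0.01 in the mean of the lines and was not called. DNA replication genes fell, 24 of 32 down and 0 up (25 and 0 adjusted over the list alone; median -0.82, camera adjusted p = 5.0e-11), with CDC45 at -2.10 ± 0.11 and RRM2 at -2.06 ± 0.13. G2/M genes were called downward, 16 of 32 down and 6 up (17 and 8 adjusted over the list alone; median -0.32, adjusted p = 0.021, and adjusted p = 0.12 with an estimated correlation).

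SnoRNA host genes rose in RDES (0.75, adjusted p = 0.00011), SF3a/SF3b and U2 factors rose (0.33, adjusted p = 0.0091), and EWS-FLI1-activated and oxidative phosphorylation genes fell (-0.33 and -0.16, adjusted p = 0.00020 and 0.014). Heat shock protein genes were called upward (0.32, adjusted p = 0.024, and adjusted p = 0.083 with an estimated correlation). The unfolded-protein and immediate-early lists were not called in RDES (camera adjusted p = 0.48 and 0.40). Nearest to 0 over 7 ways of scaling, the medians in RDES were -0.46 for DNA replication genes, -0.14 for G2/M genes, 0.14 for heat shock protein genes and -0.05 for oxidative phosphorylation genes. In RDES 6967 probes changed, 3418 up and 3549 down, with 370 and 482 at 2-fold or more. The split was 2071 and 3980 under median centring and 3501 and 3090 with centring on probes detected on all arrays.

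Some genes were at background in one treatment, so their fold changes are lower bounds, taken from the detection limit of those arrays. GGT1, a glutathione-degrading enzyme, was detected on 0 of 12 vehicle arrays and 12 of 12 PlaB arrays, and was at least 4.09-fold higher in SKNMC, 1.60-fold in TC32, 2.11-fold in TC71 and 1.66-fold in RDES. ITGB3BP, a centromere protein gene, was detected on 12 of 12 vehicle arrays and 0 of 12 PlaB arrays, and was at least 1.57-fold lower in TC32 and 1.55-fold lower in TC71. In RDES, SNORD13 was dim with vehicle and at least 3.34-fold higher with PlaB. FOSB, an immediate-early gene detected on 0 of 12 vehicle arrays, was at least 1.63-fold higher in SKNMC, 1.102-fold in TC32, 1.75-fold in TC71 and 1.45-fold in RDES. For HRK, PDGFRB, PHLDA1, SESN2, HERC5, IFIH1 and CORO1A a treatment was detected on 0 of 3 arrays in at least 1 line, so their values in the mean of the lines are not exact.

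The response shared by the lines was counted as probes called with the same sign in all 4. SRSF7, DBNL, PRKCB and SNHG1 were among them, with SRSF7 between -1.97 and -2.32 and PRKCB between -1.76 and -2.35. The count was 2998 probes, 1506 up (1090 genes) and 1492 down (1099 genes). Independent calls would have given 35.2 up and 47.5 down. The 4 comparisons share each probe's estimate of spread, so their calls are not independent and these numbers can be too low. The split was 579 up and 2317 down under median centring and 1761 up and 1281 down with centring on probes detected on all arrays.

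The last comparison asked whether the response to PlaB differed between the lines. RNA28SN5 had the widest range, from -3.72 in SKNMC to 2.64 in TC32, with 0.32 in TC71 and 1.78 in RDES (SE 0.34, n = 3 and 3; limma F-test adjusted p = 1.2e-10). The B-cell activating factor TNFSF13B rose in SKNMC and TC71 (1.12 and 0.89) and fell in TC32 (-1.69). MXD4, a MAX partner that opposes MYC, fell in SKNMC (-1.40) and rose in TC71 (1.15). The endothelial transcription factor SOX18 fell in SKNMC by 2.04, and its value in TC32 was 0.38, a call that held in 3 of 7 ways of scaling. RPPH1, the RNA of ribonuclease P, rose by 2.38 in SKNMC and stood at -0.08 in RDES. SH3PXD2A, GAS1 and SAMD11 fell by 1.53, 3.40 and 2.51 in SKNMC and were at 0.15, -1.27 and -0.11 in TC32.

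CDKN1A rose in SKNMC and TC71 by 1.00 ± 0.12 and 0.44 ± 0.12 and fell in TC32 and RDES by 0.83 ± 0.12 and 0.75 ± 0.12 (SE, n = 3 and 3; F-test adjusted p = 1.2e-09), with the TC71 rise not called in 1 of 7 ways of scaling. MYC fell in SKNMC and TC71 by 0.41 and 0.44 and rose in TC32 by 0.52, each call missing in 1 of 7 ways of scaling. PHF5A rose by 0.51 in SKNMC, a call missing in 1 of 7 ways of scaling (adjusted p = 0.074), and by 0.73 in TC32, and stood at -0.15 in RDES. NKX2-2 fell by 0.95 in SKNMC and had a value of -0.23 in RDES. The test called 7438 probes (42.4%), and 1606 of them had a range of 2-fold or more. Calls of opposite sign in 2 lines were made for 784 probes. Pairwise tests called 4796 probes between SKNMC and TC32, 4135 between SKNMC and TC71, 4165 between SKNMC and RDES, 2883 between TC32 and TC71, 1980 between TC32 and RDES, and 1855 between TC71 and RDES. Correlations of log2 fold changes across probes ranged from 0.67 to 0.75 between lines.

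**Figure D4:**
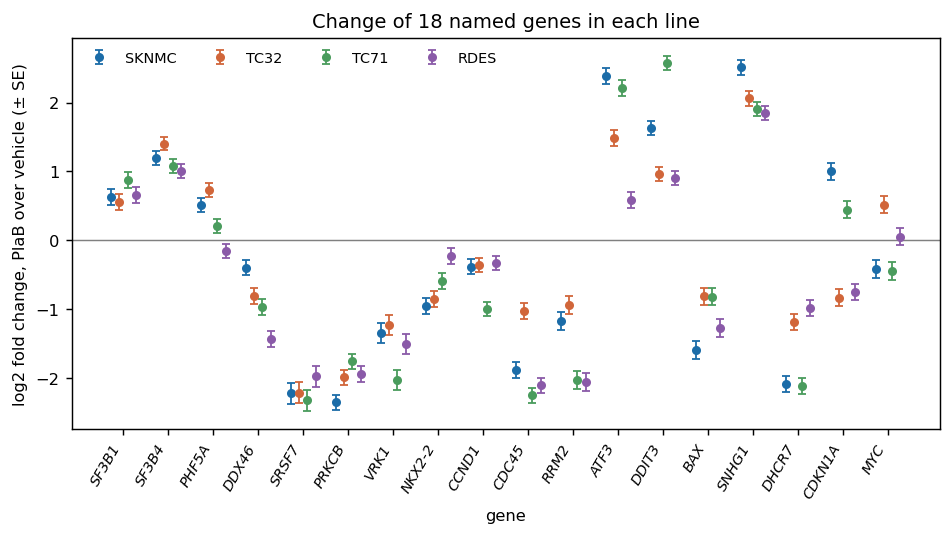
Log2 fold change (vertical axis, PlaB over vehicle) of 18 named genes in each of the 4 lines; points are limma estimates from 3 against 3 arrays and bars the SE. SRSF7, PRKCB and SNHG1 keep their direction in all 4 lines, and CDKN1A and MYC do not.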

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

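The tests of gene lists between pairs of lines and the permutation of residuals were chosen after the values of single lines had been seen, and the F-tests of single genes were planned. The results in this part stand out because the response to PlaB differed between cell lines by a test of the difference itself. The F-test called 7438 of 17557 probes. Regroupings of vehicle and PlaB arrays within lines gave at most 6692 besides the real grouping, but they remove the response itself and so do not decide whether the lines differ. With the residuals of a fit with a common response for all lines permuted over the arrays, 1 of 100 counts was as large. That was the real count, and the highest other was 46, so chance spread between these arrays can be excluded. Chance differences between cultures cannot, because the samples of a group may not be separate cultures. Of the 132 genes named in the report, 111 passed the F-test, 60 of them with a range of 2-fold or more. The number after each gene is the range of its 4 within-line log2 fold changes.

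Detection limits these ranges. Of the 7438 probes, 1876 were detected on 0 of 3 arrays of a treatment in at least 1 line, and 5562 were not so limited. Of the 111 genes 16 were limited in this way, and their ranges are not exact. In CXCL14, SNORD13, GGT1, HERC5, ESAM, CORO1A, IFIH1, FOSB, SESN2 and CLDN5 an end of the range itself rests on such a line, so a difference in the size of their response is not established. In ACTG2, SNORA68, PHLDA1, PIGP, PDGFRB and ANTXR1 another line was limited.

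RNA28SN5, the probe for 28S ribosomal RNA, had the widest range (6.37), and its second, dimmer probe stood at -0.91 in SKNMC and 0.49 in TC32. Other genes with ranges past 2 were CXCL14 (3.11), TNFSF13B (2.82), SH3PXD2A (2.67), MXD4 (2.55), GAS1 (2.496), RPPH1 (2.46), OVGP1 (2.42), SOX18 (2.41), SAMD11 (2.40), ACTG2 (2.15), H2AC19 (2.06), CD248 (2.05) and BHLHE22 (2.03). CDKN1A (1.83) rose in SKNMC and TC71 and fell in TC32 and RDES, and MYC (0.96) rose in TC32 and fell in SKNMC and TC71.

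Stress, heat shock and immediate-early genes in this group were ATF3 (1.80), DDIT3 (1.68), HSPA1B (1.58), CCN1 (1.41), DNAJB6 (1.04), SLC3A2 (0.88), DNAJA1 (0.67), PPP1R15A (0.65), FOSB (0.60) and SESN2 (0.58). Among genes of replication, the cell cycle and histones the ranges were H2AC18 (1.95), PRIM1 (1.68), H4C3 (1.37), CDC45 (1.22), RRM2 (1.12), H2AC25 (1.05), RAD51AP1 (1.03), GINS2 (0.87), UBE2C (0.83), NEK2 (0.79) and KIF11 (0.78). Small RNAs and their hosts were SNORD99 (1.58), SNORD25 (1.53), SNORA68 (1.51), SNORD13 (1.45), SNORD16 (1.01), SNORD100 (0.98), SNORA7B (0.98), SNORA3B (0.77), ZFAS1 (0.66), SNHG1 (0.66), SNORD55 (0.66) and SNHG9 (0.60).

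Splicing factors were CDC40 (1.54), CLK3 (1.07), DDX46 (1.04), PHF5A (0.88), CHERP (0.79) and HNRNPA0 (0.64). EWS-FLI1 targets were STEAP2 (0.99), VRK1 (0.80), NKX2-2 (0.72), CCND1 (0.66), PRKCB (0.60) and PHLDA1 (1.09). Collagens and other mesenchymal genes were COL3A1 (1.61), COL5A1 (1.21), COL1A1 (1.20), TAGLN (0.74), PDGFRB (0.73) and ANTXR1 (0.67). Genes of mitochondria and of lipid synthesis were NDUFAF3 (1.40), UQCC2 (1.06), ATP5PO (1.02), ATP5F1C (0.96), NDUFB5 (0.93), UQCRC1 (0.74), CCDC90B (0.81), SCD (1.44), DHCR7 (1.14), HMGCS1 (1.11), LSS (0.95), PMVK (0.89) and FADS1 (0.73). Genes of the p53 and BCL2 lists were BCL2L2 (1.31), GADD45A (0.80), AEN (0.79), BAX (0.78) and BCL2L1 (0.47).

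The remaining named genes were PI15 (1.87), P2RY11 (1.74), MSRB1 (1.72), POU3F2 (1.70), OLFM1 (1.51), CD14 (1.39), GGT1 (1.36), NUP50 (1.29), IL20RB (1.20), HERC5 (1.18), KRT18 (1.16), POU3F1 (1.05), ESAM (1.03), PIGP (1.00), KTI12 (1.00), DBNL (0.97), TMEFF2 (0.93), CORO1A (0.88), RPL37 (0.86), RASSF1 (0.80), CD79A (0.77), UBFD1 (0.70), IFIH1 (0.60), RPL7A (0.57), PDRG1 (0.51) and CLDN5 (0.50).

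Of 19 lists, 10 differed between at least 1 pair of lines (30 of 114 pairwise camera tests). The range of the medians in the 4 lines was 0.87 for G2/M genes, from 0.54 in SKNMC to -0.32 in RDES. It was 0.68 for DNA replication genes, from -0.14 in SKNMC to -0.82 in RDES, where the SKNMC median was 0.09 with centring on probes detected on all arrays. Histone genes had a range of 0.59, with 0.48 in TC71 and -0.12 in RDES. Fibroblast and mesenchymal markers had 0.52, from -0.56 in SKNMC to -0.04 in TC32, but that pair was not called (adjusted p = 0.47), and only SKNMC and TC71 (-0.19) were (adjusted p = 0.024). Heat shock protein genes had 0.47, cholesterol synthesis genes 0.39, unfolded-protein and amino-acid stress response genes 0.37 and oxidative phosphorylation genes 0.33. Immediate-early genes had 0.29 and SR proteins and hnRNPs 0.24.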

How the results depend on the processing

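Median centring on probes detected on all arrays, quantile normalization within each line, and the comparison of list directions in single lines over scalings were chosen after seeing the data. Counts of changed probes stayed within 1.5 times under every alternative run except a 2-fold minimum, which by its construction left 2154 probes in SKNMC, 944 in TC32, 1113 in TC71, 852 in RDES and 857 in the mean of the lines. With an estimated correlation 5 gene lists were called in place of 9. Leaving out each array in turn gave 8473 to 9341 probes in SKNMC, 6333 to 7277 in TC32, 6839 to 7765 in TC71, 6101 to 7039 in RDES, 11254 to 11494 in the mean, 2843 to 2978 in all 4 lines and 6710 to 7301 differing between lines, and 9 lists each time. Fold sizes depended on the background correction: without it, 50 of 102 called genes named for the mean had a log2 fold change over 1.5 times smaller (median share 0.669), against 11 under median centring and 0 under cyclic loess. Directions of values near 0 turned with the scaling. Under median centring the medians of EWS-FLI1-repressed genes (-0.19), SR proteins and hnRNPs (-0.16), histone genes (-0.064), p53 targets (-0.058), G2/M genes (-0.089), BCL2-family genes (-0.21) and ribosomal protein genes (-0.052) became negative, as did EWSR1 (-0.066) and MCL1 (-0.23). Cyclic loess gave EWS-FLI1-repressed genes -0.0077. Centring on probes detected on all arrays gave single-exon genes 0.14, interferon-stimulated genes 0.085, MYC 0.041 and CLDN5 0.15. BCL2-family genes and MCL1, their median member, ranged from -0.00077 (without RDES vehicle replicate 2) to 0.12 (without RDES vehicle replicate 1). The cause was not tested. CLDN5 missed the threshold in 20 of 24 fits without 1 array, and also without background correction, with an offset of 50, with a detection threshold of 0.01, with the replicate block and with quantile normalization within each line. EWSR1 passed it in 7 of the 24 fits, with 0.17 and adjusted p = 0.013 without TC32 vehicle replicate 1. Apart from these, no named gene in the comparison it was chosen for, and no list in the mean of the lines, gained or lost a call when 1 array was left out. List calls in single lines and the other single-line calls of named genes were not run this way. EWSR1 also passed without background correction, with an offset of 50, with 1 probe per gene, with the trend and robust prior and with both added scalings. CDKN1A (-0.31), MYC (-0.23) and MCL1 passed under median centring, and CDKN1A also passed without background correction and with quantile normalization within each line. Lists that lost their call were fibroblast markers under cyclic loess, unfolded-protein genes with centring on probes detected on all arrays, both of these without shared genes, and both with immediate-early and cholesterol synthesis genes with an estimated correlation. Among genes named for the mean of the lines, the other calls lost were those of PHF5A, RPL29, RPL37, KRT18 and CD79A under median centring and CORO1A with centring on probes detected on all arrays. Of 471 calls of named genes in single lines, 44 were missed in at least 1 of 7 ways of scaling, among them SF3B1 in TC32 (adjusted p = 0.18) and PHF5A in SKNMC (adjusted p = 0.074).

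Replicate numbers did not pair the samples: deviations from the group means of same-numbered PlaB and vehicle arrays correlated at -0.04 to 0.05, and 6 of 12 pairs correlated best with their own number. With the replicate number as a block, 9270 probes changed in SKNMC, 7115 in TC32, 7608 in TC71, 6852 in RDES, 11445 in the mean and 2972 in all 4 lines, 7187 differed between lines and 9 lists were called. The beadchip block was not run, since the columns give no chip. The series matrix was run for TC32 alone, because its values in the other lines stand under other probes in part. Fits of 6 arrays were not run for the mean, the difference between lines or the lists, and 1 probe per gene was already the form of the list tests. Signal over background limits what can be seen: 29.2% to 39.6% of probes were detected on an array.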

Other observations

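The tests on RNAs made from their own promoters, on other snoRNAs against them and on EWS-FLI1-repressed genes were chosen only after the results had been seen, as were the counts by RNA class and of genes with opposite probes and the search over all differing normalized values. Probes for small nuclear and nucleolar RNAs rose as a class, which no preset list covered. Of 104 snoRNA probes, 91 rose and 1 fell in the mean of the lines (median 0.55 log2), and of 13 snRNA probes 12 rose and 1 fell (median 0.73). For comparison, 4124 of 13369 protein-coding probes rose and 5127 fell (median -0.04), and 50 of 196 lncRNA probes rose and 58 fell. Probes for U1, U4atac, U6 and 7SK RNAs were among those that rose. Their values were 0.88 ± 0.07 for RNU1-1, 1.56 ± 0.06 for RNU4ATAC, 1.12 ± 0.05 for RNU6-1 and 1.16 ± 0.08 for RN7SK (SE). The members that fell in the mean were SNORD48 (-0.60 ± 0.06) and SNAR-A1 (-0.23 ± 0.08). The rise was weaker in RDES, where 52 of 104 snoRNA probes rose and 4 fell (median 0.30) and 6 of 13 snRNA probes rose. In SKNMC 77 snoRNA probes rose and 2 fell. In the mean, the count of rising snoRNA probes was 73 under median centring and 70 with no scaling between arrays. It was 99 with centring on probes detected on all arrays.

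Dim signal as the source was excluded: of 10000 probe sets matched on mean level none reached the median of 0.57 of the snoRNA and snRNA probes, and the highest had 0.14. Scaling could not be excluded by the bounds set beforehand. The lowest distance of the snoRNA median from that of all probes was 0.26, without background correction, against a bound of 0.3. Dropping that correction also made log2 fold changes of named genes smaller (median share 0.669). The distance was 0.52 with no scaling between arrays and with both centrings, which only shift whole arrays and so cannot change it. Under cyclic loess, with the background correction kept, it was 0.58. A candidate explanation is that introns kept in unspliced host transcripts carry snoRNA sequence to the probes. It cannot apply to RNAs made from their own promoters, which have no host intron, so their rise does not test it. Among these, 16 of 17 probes rose (15 genes, median 0.75) and SNAR-A1 fell, so that explanation alone cannot account for the whole class. It stays open for the other snoRNAs, of which 87 of 100 probes rose. Their median was lower by 0.21 (difference -0.21, permutation p = 0.24). Whether the probes read mature RNA or longer precursors was not tested, and the rise is a hypothesis about small RNA output that these arrays alone cannot settle.

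The fall of EWS-FLI1-activated genes (median -0.32) was weighed in the same way. Of 10000 gene sets matched on mean level, 2 had a median as low and the lowest had -0.34, which argues against a fall common to genes of that level. Under the other scalings the list stayed called, and its median lay at least 0.24 below that of all probes (-0.24 at the nearest). Settings that only shift whole arrays could not change this distance, which was -0.30 with both centrings and with no scaling. Only the remaining settings test the scaling, and their values argue against it as the source. Lower activity of the fusion protein stays open, because EWS-FLI1-repressed genes, which it would raise, were not called (adjusted p = 0.78), and no probe of FLI1 passed the filter.

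The deposited normalized values of SKNMC, TC71 and RDES differ from the intensities row by row. Another normalization was excluded, since the sorted values of each array matched those of the quantile-normalized intensities at 100% of ranks. The search for the differing values at other probes of the line was written for all of them but was first run only on bright ones, with all 6 values above the 90th percentile of the line (2354 probes in SKNMC, 933 in TC71 and 2514 in RDES). Of these 100% matched another probe within 0.03 log2 on all 6 arrays, and 0% did so after shuffling. Over all differing values, run later, 100% matched as well, but so did 44.7% to 48.2% after shuffling, above the bound of 10% set beforehand, so bright values stand under other probes' identifiers and for dim values this stays open. No biological explanation was tested.

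ACTB, for example, had a normalized value of 6.23 in SKNMC against 12.3 from the intensities of the same probe, and 12.3 against 12.3 in TC32. Correlations of vehicle values between lines were 0.34 to 0.73 in the normalized values, apart from 0.96 for SKNMC and RDES, and 0.95 to 0.96 in the intensities. Comparisons of single genes made from those 3 lines' normalized values would in part read other genes.

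Regrouping the arrays gave the following. In each line the 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 9276 probes in SKNMC, 7189 in TC32, 7648 in TC71 and 6967 in RDES, and the highest other split gave 1, 1, 0 and 0. For the mean of the lines the real grouping gave 11522 probes, and the highest of the other regroupings 2728. For probes changed the same way in all 4 lines it gave 2998, and the highest other 0. In both, only the real grouping of 100 within lines gave a count as large, which excludes chance spread between these arrays. Chance differences between cultures cannot be excluded, because the samples of a group may not be separate cultures. For the gene lists the real grouping was also the only one with 9 and the highest other had 8. That margin is smaller than the change between settings, with 8 lists under cyclic loess and 5 with an estimated correlation. Chance spread between these arrays can thus be excluded for the number of lists only in the setting used.

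Probes of a gene did not always move together. Of 1504 genes with at least 2 called probes, 179 (11.9%) had probes called in opposite directions. Genes picked after their values were seen were SNHG5 (2.29 and -0.15), OCIAD2 (1.66 and -0.53) and OLFM1 (-1.502 and 0.64). The RefSeq accessions attached to these probes differ for OCIAD2 and OLFM1 and are the same for SNHG5.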
